A study of Mus musculus with 54 samples.

How the data were processed

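RNA was measured with Smart-seq2, a full-length RNA-seq method for small numbers of cells, in 40 libraries of small-intestinal group 2 innate lymphoid cells (ILC2s) from C57BL/6 mice aged 8 to 12 weeks, pooled male and female per the labels. The values are TPM, a share of transcripts scaled to a fixed total per library, per gene as deposited by the authors, in 1 table for the 24 culture libraries and 1 for the 16 libraries of nILC2 and iILC2. Per the submitters' processing notes, cutadapt 2.10, STAR 2.7.5c and RSEM 1.3.3 were used with mm10. The same notes also name Bowtie2 2.2.5, SAMtools 1.10, bedtools 2.29.2, Picard 2.23.8 and deepTools 3.5.0 without a role. Reads were paired, 150 bases each, per the series text.

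The culture table listed 10799 genes and 10176 were listed for nILC2 and iILC2, with 9985 in both. The authors' filter on genes was not stated, and neither table listed a mitochondrially encoded gene. Columns therefore summed to less than the fixed total. TPM values keep no read total, so the depth of each library is unknown and no counting error or detection floor could be given. Genes are named by the symbols in the tables. Of these, 10701 and 10102 were matched to the reference annotation (GRCm38.p6, the assembly of mm10), from which the coordinates were taken.

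Samples were grouped from their titles and labels into 6 culture groups and 4 nILC2 and iILC2 groups, with 4 libraries in each. Each table was fitted alone with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(TPM + 1), with 1 mean per group and no replicate block. Genes with at least 1 TPM in at least 4 libraries of a table were tested, 10548 in the culture table and 10069 in the other. The p-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the changes of genes with few TPM. The 12 comparisons were IL-25 at 4, 48 and 72 h, the change of its effect between those times, culture time without IL-25, KO in nILC2 and in iILC2, the difference between these KO effects, and iILC2 against nILC2 in CTRL and in KO.

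Gene lists for pathways of ILC2 activation, lipid, sugar and amino acid metabolism, stress responses, retinoid metabolism, cell cycle, and marker genes of other cell types were fixed before the data were examined, 29 in all. They were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Lists with fewer than 3 tested genes were not tested. Beside the count of members called over all genes, the count adjusted over the list alone is given where it differs. Genes that IL-25 moved at least 2-fold in culture (adjusted p under 0.05) formed 6 further lists, raised or lowered at each of 3 times, that were tested in the other table. Rxrg levels were compared by two-sided exact permutation tests, for which 4 libraries against 4 allow 0.0286 as the smallest p. Agreement between comparisons was described across genes, which are not independent replicates, so no p is given for it.

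The genes named in the text followed a rule fixed with the design. It took Rxrg in every group, 12 key genes in each main comparison whatever their result, and per comparison up to 8 genes with the largest rise and up to 8 with the largest fall. The last had to be called, reach a mean of 10 TPM in the higher group, and have no overlap between the libraries of the 2 groups. Unnamed gene models and pseudogenes were left out. Up to 4 members of each list served as examples. Not every gene that the rule covers is named, key genes included. Abca1, 1 of the key genes, was not among the genes tested. Genes outside the rule that are named in the closing observations were chosen after their values were seen.

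The alternatives tried were a pseudocount of 0.1 TPM, no filter on low values, a filter of 5 TPM, rescaling by the median of ratios, quantile normalization, a fit of the compared groups alone, array weights, a block on the replicate number of the titles, the list test fry, and leaving out each library in turn. A term for Y-linked expression (Eif2s3y, Ddx3y, Kdm5d and Uty together at 5 TPM or more) was added for nILC2 and iILC2 after the data were examined. Whether libraries with the same number deviate together was tested on log2 values after removal of group means. Between nILC2 KO and iILC2 KO libraries r was 0.188, 0.102, 0.231 and 0.145 for numbers 1 to 4, all over 0.1. Same-numbered libraries of these 2 groups thus deviated together by the data, while the labels do not state a pairing. In every other pair of groups at least 1 number had r under 0.1. Shared deviations were not particular to the KO groups, as 18 of 24 same-numbered pairs of the genotype table were over 0.1. The highest was 0.253, for number 1 of nILC2 CTRL and iILC2 CTRL.

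The procedure was tested on simulated data. Of 50 genes changed by log2 1 in the nILC2 libraries, 42 were called, and of 50 changed by 0.5, 17 were called, with 4 of 9869 unchanged genes called. In the iILC2 libraries 38 and 14 of 50 were called, with 6 unchanged genes. In the culture libraries at 48 h 41 and 18 of 50 were called, with 10 of 10348 unchanged genes. The simulated noise was independent between genes, so deviations that many genes of a library share are left out, and these rates of false calls may be too low. It also took 1 spread per gene over all groups of a table. The rates for nILC2 and iILC2 therefore leave out that their real spreads differ (median SD 0.246 and 0.194). In 100 other simulations from the residuals of whole libraries, unchanged nILC2 groups gave 17.4 called genes on average and up to 581. The 14 other samples, 4 ATAC and 10 CUT&Tag, had no expression table and were not analysed here.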

Results

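The data comprised RNA profiles of ILC2s, innate lymphocytes that secrete type 2 cytokines, from mouse small intestine. In the culture experiment, 24 libraries of WT cells formed 6 groups of 4, kept for 4, 48 or 72 h with IL-2 and IL-7 and either without or with IL-25, an epithelial cytokine that activates ILC2s. In the genotype experiment, 16 libraries formed 4 groups of 4: nILC2 and iILC2, each from mice labelled CTRL and KO, with Rxrg, the gene of retinoid X receptor gamma, as the targeted gene. All 16 carried the labels IL-25 and 48 h, and the labels do not spell out the prefixes n and i. The values were TPM as deposited, so sequencing depth is unknown. The listed genes summed to between 873200 and 898025 TPM per culture library, with 9532 to 9941 genes at 1 TPM or more, and to between 849733 and 886670 TPM in the genotype experiment, with 9530 to 9864 genes. The 10 most abundant genes held 6.65% to 8.80% and 7.25% to 9.80% of the listed TPM. Values below are means ± SD of n = 4 libraries. Fold changes are log2 differences of TPM + 1.

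Rxrg itself was measured first, since it shows whether the KO libraries match their labels. In nILC2 it was 12.3, 17.4, 12.2 and 18.4 TPM in the CTRL libraries and 2.58, 1.76, 1.27 and 3.12 TPM in the KO libraries, 6.90-fold lower in KO (15.1 ± 3.29 against 2.18 ± 0.826; exact permutation p = 0.0286, n = 4). In iILC2 it was 1.72, 1.83, 1.26 and 1.68 TPM in CTRL and 0.26, 0.48, 0 and 0.38 TPM in KO, 5.79-fold lower (1.62 ± 0.250 against 0.280 ± 0.207; exact permutation p = 0.0286, n = 4). Every KO library lay below every CTRL library of its cell type. Some Rxrg signal was thus listed in 7 of 8 KO libraries. The gene lies on chromosome 1 from 167598362 to 167639623 in GRCm38.p6. In culture without IL-25, Rxrg was 32.9 ± 3.92 TPM at 4 h, 53.1 ± 7.78 at 48 h and 50.4 ± 7.45 at 72 h. With IL-25 it was 3.81-fold lower at 4 h, 14.6-fold lower at 48 h (3.65 ± 0.996 TPM) and 17.1-fold lower at 72 h (2.94 ± 1.26 TPM; exact permutation p = 0.0286 at each time, n = 4). Between the CTRL groups of the genotype experiment, iILC2 had 9.29-fold less Rxrg than nILC2 (exact permutation p = 0.0286, n = 4).

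**Figure D1:**
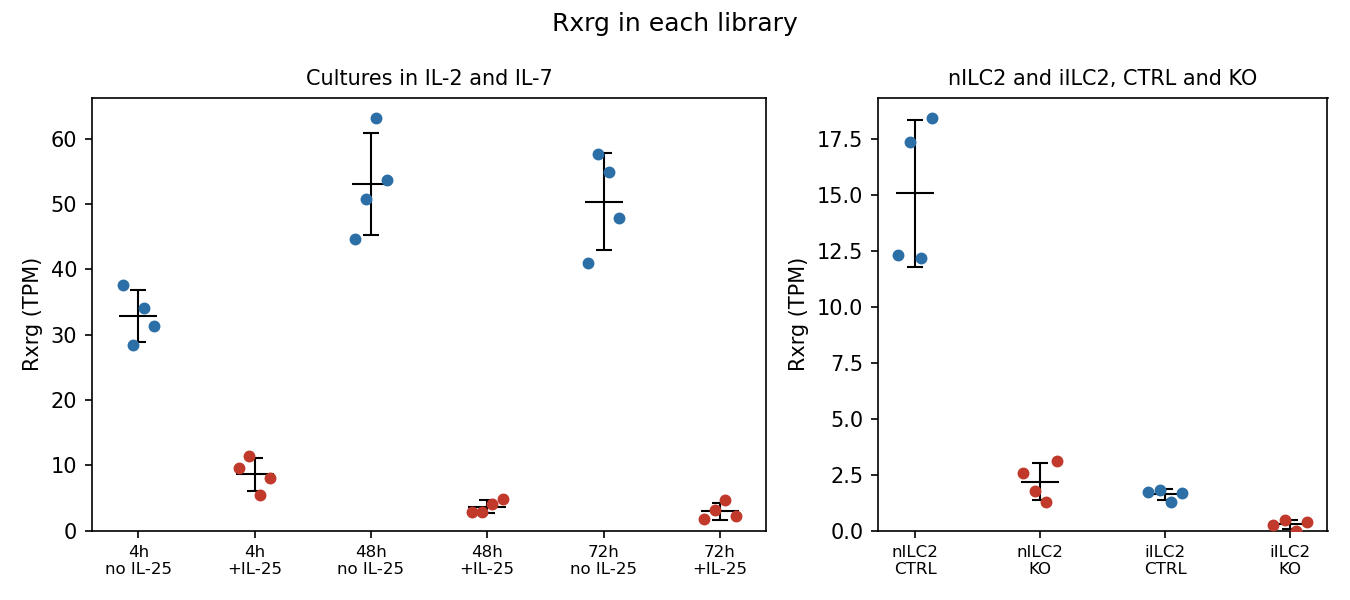
Rxrg in TPM for each library of the culture groups and of the nILC2 and iILC2 groups, with the mean and SD of 4 libraries per group. The cultures with IL-25 at 48 h average 3.65 TPM against 53.1 TPM without it, and the nILC2 KO libraries average 2.18 TPM against 15.1 TPM in CTRL.

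The culture experiment asked how ILC2s respond to IL-25 over time. After 4 h, IL-25 raised type 2 cytokine genes and lowered the gene of its own receptor subunit. Il9 was 16277 ± 1863 TPM with IL-25 and 513 ± 229 without (log2 fold change 5.07, adjusted p = 5.8e-09), Il13 was 150 ± 5.92 against 23.4 ± 3.19 (2.64, adjusted p = 5.3e-15), and Il5 was 2034 ± 218 against 360 ± 87.7 (2.52, adjusted p = 1.4e-12). Il17rb, which encodes the IL-25 receptor subunit, fell from 354 ± 21.1 to 155 ± 12.3 TPM (-1.19, adjusted p = 1.4e-10). Of 11 type 2 cytokine genes, 6 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.00051 for the list, 0.017 with an estimated correlation). Of 18 NF-kB response genes, 15 rose and 1 fell (15 and 2 adjusted over the list alone; adjusted p = 3.1e-11, and 0.022 with an estimated correlation), among them the inhibitor gene Nfkbia (1049 ± 42.5 against 333 ± 25.0 TPM), Nfkbiz (205 against 75.5), Zc3h12a (46.8 against 12.0) and the activation marker Cd83 (78.8 against 17.4). Of 7 heat shock genes, 6 rose, also 6 adjusted over the list alone (adjusted p = 8.6e-07, and 0.017 with an estimated correlation), including the chaperones Hspa8 (7459 against 4377 TPM) and Hspd1 (799 against 445).

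Among the genes with the largest rise at 4 h were also Il22 (393 ± 124 against 34.5 ± 15.8 TPM), Dgat2, an enzyme of triglyceride synthesis (412 ± 35.9 against 52.2 ± 6.75), Ankrd9 (41.1 against 5.69) and the chemokine receptor gene Ccr7 (10.9 against 1.03). The largest falls were those of Hba-a1 (7.25 ± 1.85 against 68.9 ± 5.72 TPM, log2 -3.11), Kif23 (-2.88), Cpne7 (-2.86), Oasl2 (-2.77), Nlrc3 (-2.60), Lrrc52 (-2.49), Rab19 (-2.37) and Ctla2b (-2.36). Hba-a1 encodes alpha globin, which marks red blood cell precursors, and has the near-identical copy Hba-a2, so its level is uncertain. Amino acid response genes rose in 9 of 15 cases (adjusted p = 7.2e-06, but adjusted p = 0.071 with an estimated correlation), with Mthfd2 at 91.1 against 42.7 TPM and Asns at 43.2 against 21.9. Of 13 interferon response genes, 10 fell (adjusted p = 0.0014, but adjusted p = 0.22 with an estimated correlation), including Oasl2 and Usp18 (0.795 against 4.23 TPM). Among cytokine feedback genes, 5 of 12 rose and 2 fell, 5 and 3 adjusted over the list alone (adjusted p = 0.029, lost under quantile normalization with adjusted p = 0.16, and adjusted p = 0.39 with an estimated correlation). They included Myc (600 against 274 TPM) and the survival gene Bcl2, which fell (25.5 against 105). Of 12 genes of p53 targets and apoptosis, 5 rose and 1 fell, 7 and 1 adjusted over the list alone (adjusted p = 0.0014, and adjusted p = 0.22 with an estimated correlation), among them the death receptor gene Fas (36.1 against 17.2). Elsewhere, the chemokine receptor gene Ccr4 (838 against 202) and Il2ra (584 against 253) rose.

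Sterol genes moved at 4 h in both directions. Of 24 genes of cholesterol synthesis and uptake, 11 rose and 4 fell, 12 and 4 adjusted over the list alone (adjusted p = 0.012, but adjusted p = 0.41 with an estimated correlation), with Idi1 at 187 against 103 TPM. Of 9 genes of LXR targets and cholesterol efflux, 5 fell and 1 rose, 6 and 1 adjusted over the list alone (adjusted p = 0.043, but adjusted p = 0.24 with an estimated correlation, and 0.061 with no filter on low values). The exporter gene Abcg1 fell from 9.65 ± 1.16 to 2.33 ± 0.288 TPM (log2 -1.68, adjusted p = 1.1e-10), Smpdl3a from 68.4 to 31.5, and Mylip from 14.1 to 8.38. Areg, a growth factor gene, was 16.9 ± 6.60 against 9.83 ± 2.56 TPM (0.67, adjusted p = 0.01). Its call was lost without replicate 3 of the IL-25 group (adjusted p = 0.064) and in a fit of the compared groups alone (adjusted p = 0.057). Il1rl1, the IL-33 receptor gene (124 against 120 TPM, adjusted p = 0.69), Gata3, a transcription factor gene of ILC2 identity (556 against 611, adjusted p = 0.14), and Klrg1 (340 against 340, adjusted p = 0.99) did not pass. In all, 4250 of 10548 genes were called at 4 h, 1415 higher and 2835 lower, 874 of them at least 2-fold. The median of all genes lay at -0.12, and after rescaling by the median of ratios 2233 were higher and 2103 lower, and after quantile normalization 2079 and 2082.

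At 48 h, ILC2s with IL-25 expressed genes that were near absent without it, and had less Il17rb and Gata3. Il10, an anti-inflammatory cytokine gene, was 195 ± 31.5 TPM and was listed at 0 in all 4 libraries without IL-25. The cytotoxic granule gene Gzma was 1647 ± 166 against 17.3 ± 8.28 TPM (log2 fold change 6.66, adjusted p = 6.3e-15), and Tigit, an inhibitory receptor gene, was 145 ± 3.74 against 0.945 ± 0.330 (6.24, adjusted p = 4.7e-16). Il17rb fell from 124 ± 15.6 to 18 ± 1.61 TPM (-2.72, adjusted p = 5e-18), and Gata3 from 723 ± 67.1 to 295 ± 11 (-1.29, adjusted p = 2.7e-13). Il5 (2101 ± 166 against 187 ± 13) and Il13 (200 ± 7.06 against 23.9 ± 0.627) were again higher, as were Areg (147 against 30.2) and the surface marker Klrg1 (815 against 454).

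Further large rises at 48 h were those of Tg (288 against 1.16 TPM), Tnfrsf8 (187 against 0.887), Ctla4 (73.7 against 0.160), Ccr1 (62.0 against 0.160) and Zbtb32 (51.9 against 0.203). The largest falls were those of Cd200r3 (0.652 against 73.4), Tgtp1 (2.27 against 132), Hba-a1 (11.4 against 479), Ltb, a TNF family cytokine gene (6.08 against 227), Serpinb1a (3.83 against 142), Serpina3g (6.87 against 209), Rtp4 (0.182 against 28.8) and Plxdc2 (4.86 against 137). Tgtp1, Hba-a1 and Serpina3g have near-identical copies, so their levels are uncertain. Of 16 glycolysis genes, 13 rose and 1 fell, the same adjusted over the list alone (adjusted p = 1.7e-08, but adjusted p = 0.12 with an estimated correlation), with lactate dehydrogenase Ldha at 4967 ± 257 against 1793 ± 53.4 TPM and Tpi1 at 1040 against 424. Of 14 unfolded protein response genes, 10 rose, 10 and 1 lower adjusted over the list alone (adjusted p = 9.9e-06, and adjusted p = 0.12 with an estimated correlation), including Manf (637 against 260 TPM) and Hyou1 (29.3 against 14.1). Of 13 interferon response genes, 12 fell (adjusted p = 7.4e-06, and adjusted p = 0.12 with an estimated correlation), among them Gbp2 (10.1 against 131 TPM) and Irf7 (2.04 against 19.3). Hba-a1 fell with them. Of 7 heat shock genes, 5 rose (adjusted p = 8.8e-05, and adjusted p = 0.10 with an estimated correlation), with Hspd1 at 488 against 153 and Hsp90aa1 at 1003 against 362.

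Metabolic genes rose with IL-25 at 48 h in several other lists. Amino acid response genes rose in 9 of 15 cases and fell in 3 (adjusted p = 0.00084, but adjusted p = 0.22 with an estimated correlation), with the serine synthesis enzyme Phgdh at 329 against 89.9 TPM and Asns at 45.9 against 6.19. Genes of fatty acid uptake, storage and oxidation rose in 8 of 15 cases and fell in 1 (adjusted p = 0.027, lost under quantile normalization with adjusted p = 0.17, and adjusted p = 0.35 with an estimated correlation), including Fabp5 (152 against 41.3) and the lipid-sensing receptor gene Pparg (65.6 against 24.2). Oxidative phosphorylation genes were higher in 17 of 28 cases and lower in 4, 18 and 4 adjusted over the list alone (adjusted p = 0.0042, and adjusted p = 0.41 with an estimated correlation). That list call ended under quantile normalization (adjusted p = 0.93), with Cycs at 357 against 183 TPM. Of 24 cholesterol genes, 7 rose and 1 fell (adjusted p = 0.017, but adjusted p = 0.48 with an estimated correlation), with Fdps at 289 against 146 and Pmvk at 48.1 against 23.3. Abcg1 fell from 19.2 to 12.5 TPM (log2 -0.59). Of 20 genes of ILC2 identity and receptors, 12 fell and 3 rose, 14 and 3 adjusted over the list alone (adjusted p = 0.0052, but adjusted p = 0.41 with an estimated correlation), including the transcription factor gene Rora (36.5 against 179). Il1rl1 (120 against 107 TPM, adjusted p = 0.24) did not pass. In all, 5280 genes were called, 2254 higher and 3026 lower, 1378 of them at least 2-fold. The split became 2770 higher and 2647 lower after the median of ratios and 2586 and 2574 after quantile normalization.

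At 72 h, the granule genes Gzma and Gzmb and a tumour necrosis factor receptor gene were among the largest rises with IL-25. Gzma was 4402 ± 574 against 5.52 ± 4.63 TPM (log2 fold change 9.61, adjusted p = 4.2e-18), Gzmb was 11100 ± 857 against 94.5 ± 39.8 (6.95, adjusted p = 2.7e-13), and the costimulatory receptor gene Tnfrsf9 was 1093 ± 56.0 against 6.29 ± 3.18 (7.33, adjusted p = 3.8e-19). Il17rb was 12.1 ± 1.32 against 141 ± 8.86 TPM (-3.44, adjusted p = 4.2e-20). Il5 (3160 ± 421 against 206 ± 51.8), Il13 (338 ± 60.5 against 31.1 ± 4.16) and Areg (378 ± 45.2 against 35.3 ± 9.23) were higher. So were Il1rl1 (172 against 102) and Klrg1 (930 against 482), and Gata3 was lower (523 against 877). Il10 (138 ± 14.4 against 0.0950 ± 0.190), Tnfrsf8 (139 against 0.568), Ctla4 (116 against 0.522), Ccr1 (97.7 against 0.260) and Tg (131 against 1.23) again rose. Hba-a1 (13 against 622), Hba-a2 (1.44 against 61.9), Serpinb1a (3.40 against 156), Plxdc2 (3.90 against 159), Cd200r3 (3.10 against 135), Tgtp1 (4.26 against 162), Lpcat2 (0.752 against 42.5) and Ltb (13.9 against 318) fell.

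Sugar, amino acid and sterol genes were called in most members at 72 h. Of 16 glycolysis genes, 15 rose and 1 fell, the same adjusted over the list alone (adjusted p = 2.3e-21, and 0.019 with an estimated correlation), with the lactate exporter gene Slc16a3 at 272 ± 18.8 against 42.8 ± 9.52 TPM, the glucose transporter gene Slc2a3 at 38.5 against 5.76 and Pgk1 at 1581 against 423. Of 15 amino acid response genes, 12 rose and 2 fell (adjusted p = 7.3e-08, and 0.034 with an estimated correlation), with Asns at 48.5 against 4.55. Of 14 unfolded protein response genes, 12 rose and 1 fell (adjusted p = 5e-10, and 0.034 with an estimated correlation), with Manf at 691 against 249. Among 15 inhibitory and costimulatory receptor genes, 6 rose and 5 fell, 7 and 5 adjusted over the list alone (adjusted p = 0.0018, and 0.049 with an estimated correlation), with Tigit at 134 against 2.19. Of 24 cholesterol genes, 15 rose and 1 fell, 17 and 1 adjusted over the list alone (adjusted p = 8.6e-08, but adjusted p = 0.068 with an estimated correlation), including Fdps (432 ± 16.9 against 130 ± 17.2 TPM) and Insig1 (53.9 against 29.4). Abcg1 (18.4 against 20.1, adjusted p = 0.46) did not pass. Fatty acid synthesis genes rose in 5 of 11 cases and fell in 2 (adjusted p = 0.031, and adjusted p = 0.31 with an estimated correlation), with Scd2 at 93.9 against 16.6. That call ended under both rescalings (adjusted p = 0.064 and 0.059). Immediate early genes rose in 9 of 16 cases and fell in 2 (adjusted p = 0.0022, but adjusted p = 0.17 with an estimated correlation), with Ier3 at 17.0 against 2.75. Interferon response genes fell in 8 of 13 cases (adjusted p = 0.0018, but adjusted p = 0.20 with an estimated correlation), beside the fall of Hba-a1 already given. Ribosomal protein genes were lower in 35 of 76 cases and higher in 4 (adjusted p = 0.023, lost under the median of ratios with adjusted p = 0.31, and adjusted p = 0.66 with an estimated correlation). In all, 5113 genes were called, 1610 higher and 3503 lower. The median of all genes lay at -0.20, and the split became 2646 higher and 2155 lower after the median of ratios and 2162 and 2475 after quantile normalization.

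**Figure D2:**
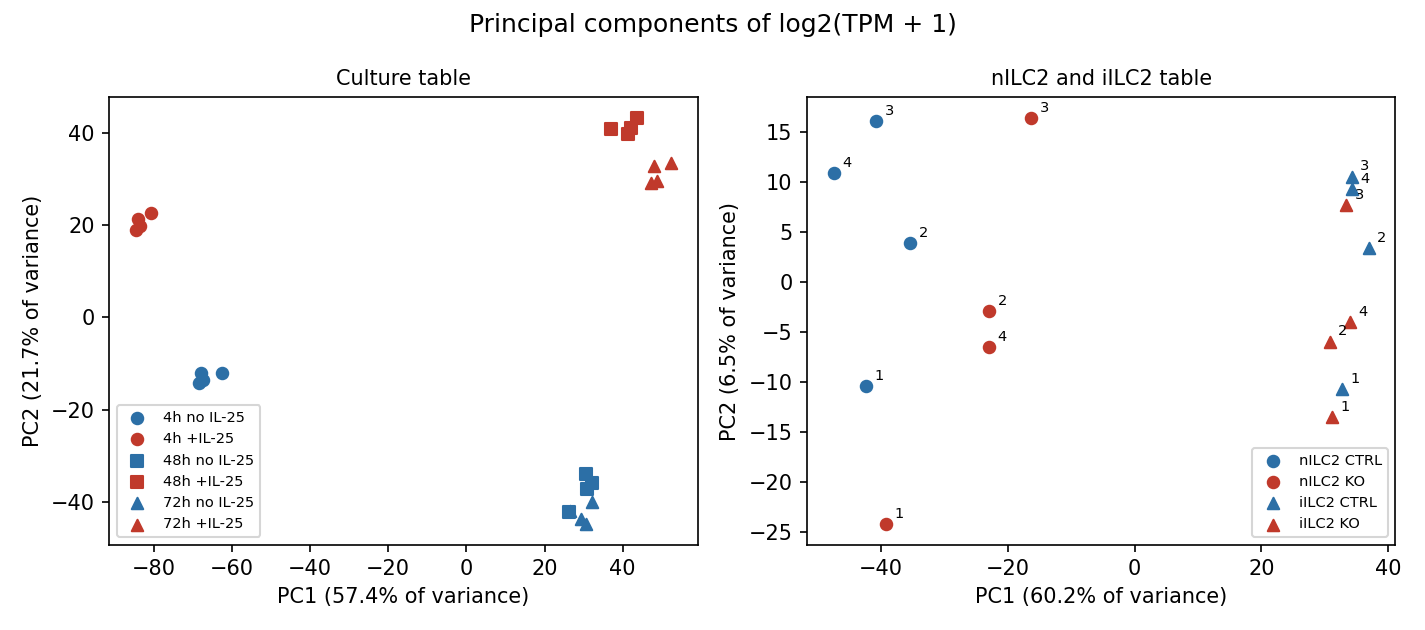
Principal components 1 and 2 of log2(TPM + 1) for each library, with the culture table and the genotype table computed apart. Component 1 holds 57.4% of the variance of the culture libraries and 60.2% in the genotype experiment, where the nILC2 libraries lie at -47.5 to -16.3 and the iILC2 libraries at 30.8 to 36.9.

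Whether the response to IL-25 changed with time was tested as the difference of its effects. From 4 to 48 h, the effect on NF-kB response genes became lower. That on Tnf moved from 1.17 to -1.81 (difference -2.98, adjusted p = 3.7e-10), on Relb from 0.76 to -1.93 (-2.68, adjusted p = 2e-11), on Ltb from -0.49 to -5.04 (-4.54, adjusted p = 1.7e-11) and on Cd83 from 2.18 to -0.33 (-2.51, adjusted p = 6.4e-07). Of 18 such genes, 17 had a lower effect at 48 h and 1 a higher one, the same adjusted over the list alone (adjusted p = 1.5e-14, and 0.022 with an estimated correlation). The effects on Rora (0.60 to -2.27), Il17rb (-1.19 to -2.72), Gbp2 (-0.15 to -3.51) and Dgat2 (2.96 to 1.23) also became lower. Glycolysis genes had a higher effect in 14 of 16 cases (adjusted p = 1.1e-10), fatty acid uptake, storage and oxidation genes in 10 of 15 (adjusted p = 0.00027), and unfolded protein response genes in 9 of 14, 10 adjusted over the list alone (adjusted p = 2.2e-06). With an estimated correlation each of these 3 lists had adjusted p = 0.091. Their examples are Ldha (0.15 to 1.47), Tpi1 (0.04 to 1.29), Pparg (-0.42 to 1.39), Fabp5 (0.50 to 1.86), Pdia6 (-0.02 to 1.00) and Manf (0.28 to 1.29). In all, 2938 genes had a different effect, 1812 higher and 1126 lower at 48 h. The split became 1688 higher and 1430 lower after the median of ratios and 1546 and 1407 after quantile normalization.

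From 48 to 72 h, the effect on glycolysis genes and on the granule genes Gzma and Prf1 grew, and that on heat shock genes shrank. Slc2a3 moved from 0.74 to 2.55 (difference 1.81, adjusted p = 4.7e-05), Slc16a3 from 1.3 to 2.67 (1.37) and Pgk1 from 0.97 to 1.90 (0.93), and 14 of 16 glycolysis genes had a higher effect (adjusted p = 6.1e-18, and 0.014 with an estimated correlation). Of 7 heat shock genes, 5 had a lower effect (adjusted p = 8.6e-06, and 0.014 with an estimated correlation), including Hspd1 (1.67 to 0.58) and Hsp90aa1 (1.47 to 0.63). Of 8 genes of ILC1, ILC3 and NK cells, 3 had a higher effect, 4 adjusted over the list alone (adjusted p = 0.00048, and 0.014 with an estimated correlation), including Gzma (6.66 to 9.61) and Prf1 (1.58 to 2.99). Among 4 epithelial markers, 1 had a higher effect, 3 adjusted over the list alone (adjusted p = 0.0034, and 0.023 with an estimated correlation). Tnfrsf9 (4.28 to 7.33), Fdps (0.98 to 1.74) and Scd1 (0.95 to 2.00) moved up as well. Scd1 was listed at 0 in 3 of 4 libraries without IL-25 at 72 h, and its call was lost with a pseudocount of 0.1 TPM (adjusted p = 0.068). In all, 1553 genes had a different effect, 551 higher and 1002 lower at 72 h. After the median of ratios the split was 866 higher and 606 lower, and after quantile normalization 748 and 652. Across genes, which are not independent replicates, the effects at 4 and 48 h correlated by r = 0.44 and those at 48 and 72 h by r = 0.83.

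The cultures without IL-25 also changed between 4 and 48 h, and cell division genes led that change. All 25 cell cycle genes rose, also 25 adjusted over the list alone (adjusted p = 2.9e-30, and 0.0085 with an estimated correlation), with Ube2c at 387 ± 131 against 1.3 ± 1.21 TPM, Ccnb2 at 149 ± 29.9 against 0.242 ± 0.219 and Birc5 at 360 ± 74.1 against 2.72 ± 1.82. Hist1h2ap (3167 against 23.5), Stmn1 (684 against 4.82), Pclaf (204 against 1.5) and Lgals1 (1144 against 13.3) rose too, and H2ac11 was 98.2 TPM at 48 h and listed at 0 in all 4 libraries at 4 h. Histone genes such as these have near-identical copies, so their levels are uncertain. Calca, the gene of the neuropeptide CGRP, fell from 2785 ± 86.4 to 13.7 ± 3.04 TPM (log2 -7.59, adjusted p = 2.1e-20), Il9 from 513 to 2.60, Pdzk1ip1 from 45.9 to 0.115, Tnfrsf9 from 256 to 6.05, Trf from 105 to 2.00, H2ac19 from 44.5 to 2.44, Ramp3 from 90.3 to 2.83 and Irf4 from 102 to 3.46. NF-kB response genes fell in 14 of 18 cases (adjusted p = 0.001, but adjusted p = 0.28 with an estimated correlation), with Cd83 at 0.297 against 17.4 TPM. Cholesterol genes fell in 18 of 24 cases and rose in 2 (adjusted p = 0.0006, but adjusted p = 0.28 with an estimated correlation), with Hmgcs1 at 25.4 against 122. Unfolded protein response genes fell in 12 of 14 cases (adjusted p = 6.3e-05, but adjusted p = 0.19 with an estimated correlation), with Hspa5 at 375 against 1043. In all, 6793 genes were called, 2094 higher and 4699 lower. The median of all genes lay at -0.28, and the split became 3277 higher and 3060 lower after the median of ratios and 2821 and 3620 after quantile normalization.

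Between 48 and 72 h without IL-25, few genes moved. Id3, a transcriptional regulator gene, was 59.3 ± 4.46 against 24.9 ± 3.62 TPM (log2 1.22, adjusted p = 0.0034), and Ccr2, a chemokine receptor gene, was 84.7 ± 18 against 43.4 ± 7.47 (0.94, adjusted p = 0.022). Serpina3f (1.02), Adora2b (0.86), Htr1b (0.79), Psen2 (0.57), Cbr1 (0.55) and Sla (0.55) were higher. H2bc12 (-0.93), Cd160 (-0.90), Ifitm2 (-0.62), Nasp (-0.44), Epcam (-0.42), Pold2 (-0.37) and Hint1 (-0.23) were lower. In all, 40 genes were called, 30 higher and 10 lower. After the median of ratios there were 15 higher and 32 lower, and after quantile normalization 38 and 48. The count fell to 21 without replicate 1 at 48 h, 12 without replicate 2 and 22 without replicate 4, and to 26, 11 and 17 without replicates 2, 3 and 4 at 72 h. Camera called 8 lists, and with an estimated correlation each had an adjusted p of 0.26 or more. Each of the 15 genes named here lost its call in at least 1 alternative, and leaving out a single library ended up to 11 of these calls (adjusted p from 0.051 for Ifitm2 to 0.20 for Hint1 without replicate 2 at 48 h, and from 0.051 for Htr1b to 0.12 for Pold2 without replicate 3 at 72 h).

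The genotype experiment asked what differs between KO and CTRL ILC2s. The labels give pooled males and females, but Y-linked genes were near absent from 6 of the 16 libraries, with Eif2s3y at 0 to 0.57 TPM, against 63.3 to 99.4 TPM in the other 10. These were CTRL replicate 2 and KO replicates 1 and 2, in nILC2 and in iILC2 alike.

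In nILC2, KO libraries had more Clnk, Nkg7 and Tigit and less of the chemokine gene Ccl1. Clnk, a signalling adaptor gene, was 18.6 ± 4.68 TPM in KO and 5.41 ± 1.53 in CTRL (log2 fold change 1.62, adjusted p = 0.00015), Nkg7, a granule membrane gene, was 94.0 ± 20.8 against 36.0 ± 14.3 (1.40, adjusted p = 0.0011), and Tigit was 23.9 ± 1.70 against 10.8 ± 0.863 (1.07, adjusted p = 0.00014). Fcer1g (28.4 ± 5.49 against 10.1 ± 5.48), Paqr4 (30.9 against 11.9), Rom1 (15.7 against 6.84), Runx2 (13.9 against 6.37) and S100a6 (93.7 against 51.0) were also higher. Besides Rxrg (-2.35, adjusted p = 1.2e-05), the largest falls among genes of at least 10 TPM without overlap between libraries were those of Ccl1 (4.26 ± 3.30 against 15.6 ± 6.84 TPM, -1.75, adjusted p = 0.0098), Rln3 (11 against 31.7), Cavin1 (6.06 against 16.2), Cd6 (17.8 against 40.8), Nrp1 (14.6 against 30.8), Kmo (12.7 against 26.7) and the epithelial marker Epcam (9.96 against 20.8). Il17rb (209 ± 25.5 against 286 ± 31.6 TPM, -0.45, adjusted p = 0.034), Gata3 (218 ± 25.4 against 282 ± 13.4, -0.37, adjusted p = 0.038) and Id2 (519 against 755, -0.55) were lower by less. So were the LXR target Mylip (6.91 against 13.3) and Ahr (9.53 against 17.5). Psat1 (169 against 119), Shmt2 (161 against 122) and Cox5a (545 against 423) were higher. The cytokine genes Il5 (26.5 against 32.3 TPM, adjusted p = 0.46), Il13 (4.34 against 3.04, adjusted p = 0.51) and Areg (5.35 against 7.03, adjusted p = 0.60) did not pass. Neither did Il1rl1 (41.9 against 66.8, adjusted p = 0.18), Klrg1 (603 against 689, adjusted p = 0.16), Abcg1 (28.7 against 41.0, adjusted p = 0.055), Ltb (588 against 903, adjusted p = 0.073), Fdps (123 against 80.6, adjusted p = 0.050) and Rrm2 (370 against 274, adjusted p = 0.17).

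In all, 155 of 10069 genes were called for KO in nILC2, 95 higher and 60 lower, 36 of them at least 2-fold. After rescaling by the median of ratios 204 were higher and 68 lower. The count was 317 with the replicate block, 275 with array weights, 82 with a pseudocount of 0.1 TPM and 5 in a fit of the compared groups alone, 2 higher and 3 lower. With a term for Y-linked expression, added after the data were examined, 87 were called, and Gata3, Rln3, Kmo, Shmt2 and Ahr no longer passed (adjusted p from 0.054 to 0.062). The count changed with every library left out. It rose to 1003 without KO replicate 1 and to 407 without CTRL replicate 2. Leaving out CTRL replicates 1, 3 and 4 gave 65, 51 and 12, and leaving out KO replicates 2, 3 and 4 gave 26, 24 and 45. The excess of higher genes turned without these KO libraries, to 7 higher and 19 lower, 7 and 17, and 21 and 24, and was 6 and 6 without CTRL replicate 4. Of the 24 genes named as higher or lower, Rxrg, Clnk and Tigit passed in every alternative. Without CTRL replicate 4 the call of 17 was lost (adjusted p from 0.057 for Fcer1g to 0.15 for Ahr), and without KO replicate 3 that of 16 (from 0.056 for Cavin1 to 0.13 for Epcam). Leaving out CTRL replicates 1 or 3, or KO replicates 2 or 4, ended 11, 13, 14 and 14 of these calls, and leaving out CTRL replicate 2 ended that of Kmo (adjusted p = 0.056). Il17rb was lost without CTRL replicates 3 or 4 or KO replicates 3 or 4 (adjusted p from 0.082 to 0.12), and Gata3 without any 1 of 6 libraries (0.059 to 0.12). Without KO replicate 1, Abcg1 (adjusted p = 0.0061), Fdps (0.0027), Ltb (0.031) and Rrm2 (0.011) passed, and without CTRL replicate 2 Abcg1 (0.028), Fdps (0.034) and Ltb (0.042) passed. With the replicate block Abcg1 (0.047), Fdps (0.022) and Ltb (0.039) passed too. So did Abcg1 and Fdps after the median of ratios (0.048 and 0.028) and with array weights (0.038 and 0.029), Fdps and Ltb after quantile normalization (0.039 and 0.032), and Fdps with the Y-linked term (0.049).

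At the preset correlation of camera, the cell cycle, oxidative phosphorylation and glycolysis lists shifted up in nILC2 KO libraries. The ribosomal, NF-kB response, cytokine feedback, ILC2 identity and immediate early lists shifted down. Among 35 splits of the nILC2 libraries 2 called 11 lists, so chance is not excluded. Camera called 11 lists at its preset correlation, and with an estimated correlation each of these had an adjusted p of 0.34 or more. By fry 4 of the 11 passed, those of oxidative phosphorylation, glycolysis, NF-kB response and cytokine feedback genes. Among 25 cell cycle genes the median change was 0.36, with 0 called over all genes and 18 higher adjusted over the list alone (adjusted p = 2e-11). Oxidative phosphorylation genes had 1 of 28 called and 14 adjusted over the list alone (adjusted p = 3.2e-09), and glycolysis genes 1 of 16 and 9 (adjusted p = 7.3e-07). Ribosomal protein genes were lower, with 1 of 76 called and 15 lower and 1 higher adjusted over the list alone (adjusted p = 1.2e-11). The NF-kB response (0 of 18 called, 3 lower adjusted over the list alone; adjusted p = 0.0011), cytokine feedback (0 of 12 and 3; adjusted p = 0.0011), ILC2 identity and receptors (3 of 20 and 4; adjusted p = 0.0024) and immediate early genes (0 of 11 and 0; adjusted p = 0.035) also shifted down. Amino acid response, cholesterol and unfolded protein response genes shifted up (adjusted p = 0.035, 0.031 and 0.036), the amino acid and unfolded protein lists not under quantile normalization (adjusted p = 0.059 and 0.41) or with a filter of 5 TPM (0.054 and 0.064). The unfolded protein list was also lost with the replicate block (adjusted p = 0.051) and in a fit of the compared groups alone (0.052), and the immediate early list with the Y-linked term (0.068). The genes that IL-25 moved in culture at 48 and 72 h shifted in the same direction in nILC2 KO libraries at the preset correlation of camera, and those raised at 4 h shifted the other way. Of the genes lowered at 48 h in culture, 776 were tested here, with a median change of -0.23 and 25 lower and 3 higher (59 lower and 6 higher adjusted over the list alone; adjusted p = 2.3e-15, but adjusted p = 0.062 with an estimated correlation). Of those raised at 48 h, 446 were tested, with 16 higher and 1 lower (54 higher and 5 lower adjusted over the list alone; adjusted p = 1.9e-08, but adjusted p = 0.16 with an estimated correlation). The lists of 72 h gave adjusted p = 4.1e-15 for the lowered and 3.8e-08 for the raised genes, with adjusted p = 0.062 and 0.11 with an estimated correlation. Both lists of 4 h shifted down (adjusted p = 0.0032 for the lowered and 0.048 for the raised genes), each with adjusted p = 0.22 with an estimated correlation and 0.14 by fry. The call of the raised genes of 4 h was lost with a pseudocount of 0.1 TPM (adjusted p = 0.087), quantile normalization (0.073) and the Y-linked term (0.082). Across genes, the effects of IL-25 at 48 h and of KO in nILC2 correlated by r = 0.37, and 93 of 107 genes called in both had the same sign.

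In iILC2, KO and CTRL libraries had close levels of the key genes. Il17rb was 114 ± 10 TPM in KO and 119 ± 9.58 in CTRL, Gata3 was 169 ± 9.26 against 167 ± 15.7, and Klrg1 was 589 ± 45.7 against 583 ± 31.6 (adjusted p = 1 for each). Rxrg itself, at 0.280 against 1.62 TPM, reached a log2 fold change of -1.04 with adjusted p = 0.44 over all genes. Il5 (3.44 against 2.73), Il13 (3.96 against 4.49), Areg (0.530 against 0.608), Il1rl1 (3.62 against 3.49), Abcg1 (13.8 against 15.8) and Cox8a (1658 against 1652) did not pass (adjusted p = 1 for each). limma called 0 genes at the adjusted threshold, with 328 at an unadjusted p under 0.05. Among 3 epithelial markers camera gave adjusted p = 0.0037 for a shift down, with 0 called in all and 0 adjusted over the list alone, and adjusted p = 0.089 with an estimated correlation. Lgals4 was 6.50 against 9.42 TPM. Oxidative phosphorylation genes had adjusted p = 0.019 for a shift up of 0.04 at the median, and adjusted p = 0.84 with an estimated correlation. None of the 6 culture lists was called by camera (smallest adjusted p = 0.15). The difference between the KO effects in iILC2 and nILC2 was also tested directly, and limma called 0 genes, with 1059 at an unadjusted p under 0.05. For Rxrg that difference was 1.31 (adjusted p = 0.16). With a term for Y-linked expression 5 genes were called, with the replicate block 8, with array weights 21 and after quantile normalization 1. Without nILC2 KO replicate 1 the count was 132 and Rxrg passed (adjusted p = 0.039). Without nILC2 CTRL replicate 2 it was 5, and without iILC2 CTRL replicate 2 it was 2. Camera called 9 lists for that difference, each with an adjusted p of 0.39 or more with an estimated correlation. The 6 culture lists were called as well, with adjusted p from 0.056 to 0.19 with an estimated correlation and from 0.056 to 0.24 by fry. Across genes, the KO effects in nILC2 and iILC2 correlated by r = 0.07, and 91 of the 155 genes called in nILC2 had the same sign in iILC2.

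iILC2 and nILC2 differed in many more genes than KO and CTRL. In CTRL, iILC2 had far less of the type 2 cytokine and receptor genes and more of the granule gene Gzma and of cell division genes. Il5 was 2.73 ± 0.810 against 32.3 ± 5.64 TPM (log2 fold change -3.17, adjusted p = 8.9e-10), Il1rl1 was 3.49 ± 2.11 against 66.8 ± 10.6 (-4.01, adjusted p = 4.2e-09), Il17rb was 119 ± 9.58 against 286 ± 31.6 (-1.25, adjusted p = 1.5e-08), and Gzma was 2156 ± 458 against 257 ± 96.4 (3.13, adjusted p = 5.2e-06). Of 8 type 2 cytokine genes, 7 were lower, also 7 adjusted over the list alone (adjusted p = 0.00015, but adjusted p = 0.064 with an estimated correlation). They included Areg (0.608 against 7.03) and Ccl1, which was 15.6 ± 6.84 TPM in nILC2 and listed at 0 in all 4 iILC2 libraries. Of 20 genes of ILC2 identity and receptors, 16 were lower and 2 higher (adjusted p = 4.1e-07, but adjusted p = 0.13 with an estimated correlation), with Il2ra at 1.71 against 53.7 TPM, Il7r at 25.9 against 313, Arg1 at 19.8 against 241 and Gata3 at 167 against 282. Of 18 NF-kB response genes, 14 were lower and 2 higher (adjusted p = 4.1e-07, but adjusted p = 0.064 with an estimated correlation), with Cd83 at 1.35 against 52.7, Relb at 3.71 against 37.6 and Ltb at 23.1 against 903. Of 12 cytokine feedback genes, 8 were lower and 1 higher (adjusted p = 2.6e-05, but adjusted p = 0.064 with an estimated correlation), with Cish at 2.17 against 63.2 and Bcl2 at 3.43 against 45.3. Of 11 immediate early genes, 6 were lower (adjusted p = 0.0038, but adjusted p = 0.22 with an estimated correlation), with Nr4a1 at 2.05 against 60.0.

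All 25 cell cycle genes were higher in iILC2 than in nILC2 of CTRL mice, also 25 adjusted over the list alone (adjusted p = 3.4e-13, but adjusted p = 0.22 with an estimated correlation), including Ccnb2 (329 ± 20.5 against 126 ± 21.7 TPM), Birc5 (519 against 208) and Rrm2 (647 against 274). Oxidative phosphorylation genes were higher in 24 of 28 cases and lower in 1 (adjusted p = 1.2e-09, lost under quantile normalization with adjusted p = 0.15, and adjusted p = 0.22 with an estimated correlation), with Ndufa1 at 615 against 366 and Cox5a at 679 against 423. Ribosomal protein genes were lower in 67 of 76 cases and higher in 1, 69 and 1 adjusted over the list alone (adjusted p = 1.2e-19, but adjusted p = 0.22 with an estimated correlation), with Rps24 at 3578 against 6090 and Rps27 at 5101 against 8634. Cholesterol genes were higher in 12 of 24 cases and lower in 1, 13 and 1 adjusted over the list alone (adjusted p = 0.0041, but adjusted p = 0.46 with an estimated correlation), with Acat2 at 41.1 against 20.6 TPM and Ebp at 99.2 against 55.5. Abcg1 (15.8 against 41.0), Klrg1 (583 against 689) and Cd3g (14.1 against 63.8) were lower, and Il13 (4.49 against 3.04, adjusted p = 0.38) did not pass. The largest rises were those of Ifi27l2a (306 ± 95.9 against 19.9 ± 9.10), Nkg7 (439 ± 43.0 against 36.0 ± 14.3), Pygm (27.5 against 1.5), Scin (50.5 against 3.79), Id3 (22 against 1.3), Avil (27.1 against 1.88), Hsbp1l1 (29.5 against 2.46) and Ggt1 (99.3 against 9.69). The largest falls were those of Dgat2 (4.54 ± 2.26 against 651 ± 79.0), Lpcat2 (0.0975 against 57.8), Ltb, Lilrb4a (0.645 against 50.1), Cd6 (0.427 against 40.8), Sdc4 (0.150 against 30.4), Serpina3g (5.80 against 169) and Nrp1 (0.340 against 30.8). In all, 4582 genes were called, 2204 higher and 2378 lower, and after the median of ratios 2374 and 2325, after quantile normalization 2294 and 2001, and with a filter of 5 TPM 2103 and 1914.

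In KO mice, iILC2 differed from nILC2 in largely the same genes. Dgat2 was 4.34 ± 1.53 against 404 ± 88.4 TPM (log2 -6.27, adjusted p = 4.7e-11), Ltb was 28 ± 4.28 against 588 ± 46.0 (-4.35), Gzma was 1640 ± 371 against 293 ± 213 (2.78) and Nkg7 was 504 ± 28.2 against 94.0 ± 20.8 (2.44). Ifi27l2a (3.02), Ms4a4b (2.54), Id3 (2.54), Ggt1 (2.53) and Rcn3 (2.52) were higher, and Lilrb4a (-4.97), Lpcat2 (-4.43), Stab2 (-4.29), Serpina3g (-4.11), Cd83 (-4.01) and Syne4 (-3.92) were lower. Lilrb4a and Serpina3g have near-identical copies, so their levels are uncertain. Of 8 type 2 cytokine genes, 7 were lower (adjusted p = 1e-05, and 0.044 with an estimated correlation), and of 18 NF-kB response genes 14 were lower and 1 higher, 14 and 2 adjusted over the list alone (adjusted p = 5.2e-08, and 0.044 with an estimated correlation). In all, 3161 genes were called, 1391 higher and 1770 lower, and after the median of ratios 1646 and 1625, and after quantile normalization 1399 and 1390. Of the 2742 genes called in both genotypes, 2741 had the same sign, and across genes the differences correlated by r = 0.90. The culture lists were tested in both genotypes too. Genes lowered by IL-25 at 72 h were lower in iILC2 in 443 of 700 cases and higher in 57 in CTRL (adjusted p = 7.6e-21, and 0.012 with an estimated correlation), and lower in 354 and higher in 55 in KO (adjusted p = 4e-16, and 0.028 with an estimated correlation). Genes raised at 4 h were lower in 63 of 121 cases and higher in 14 in CTRL (adjusted p = 7.4e-08, and 0.012 with an estimated correlation). Those raised at 48 h were higher in 149 of 446 cases and lower in 86 in CTRL (camera adjusted p = 0.016, but 0.48 with an estimated correlation). In KO they were higher in 88 and lower in 100, and the list was not called (adjusted p = 0.73). Those raised at 72 h shifted up in CTRL and KO (adjusted p = 1.5e-05 and 0.0057), but not with an estimated correlation (0.17 and 0.43). Across genes, the effect of IL-25 at 48 h and the CTRL difference correlated by r = 0.37.

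Because KO and iILC2 could be set against the same nILC2 CTRL libraries, the 2 differences were compared. Of 139 genes called for KO in nILC2 and for iILC2 against nILC2 in CTRL, 85 were higher in both, 52 were lower in both and 2 moved apart. Independent lists of these sizes would share 20.8 and 14.2, which leaves out the shared CTRL libraries. Simulated unchanged groups with shared CTRL libraries had 0.03 and 0 such genes on average, which leaves out the effects. With the iILC2 difference kept and KO unchanged, the simulated means were 4.84 and 3.2, and the highest 298 and 115. With the CTRL libraries split in 2 sets, 1 for each difference, 2 to 276 genes were higher in both and 4 to 87 lower, where independent lists would share 0.820 to 58.8 and 0.792 to 20. Nkg7, Cd6, Nrp1, Ccl1, Il17rb and Gata3 were among the genes that moved the same way. Across genes, which are not independent replicates, the differences correlated by r = 0.62. The nILC2 CTRL libraries enter both differences. Simulations with both groups unchanged gave a mean r of 0.54 (-0.26 to 0.91), but they leave out the iILC2 difference, so 0.54 is no baseline for 0.62. With the iILC2 difference kept, KO unchanged and CTRL shared, the median simulated covariance across genes was 0.0233, against 0.140 observed. Of 100 such simulations, 5 reached 0.140. With the nILC2 CTRL libraries split in 2 sets, r was 0.37 to 0.51. Along the axis from nILC2 to iILC2, the KO libraries scored -5.28, 9.72, 15.8 and 9.75 and the CTRL libraries -8.31, -1.91, -6.97 and -12.8 (exact permutation p = 0.0571, n = 4).

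**Figure D3:**
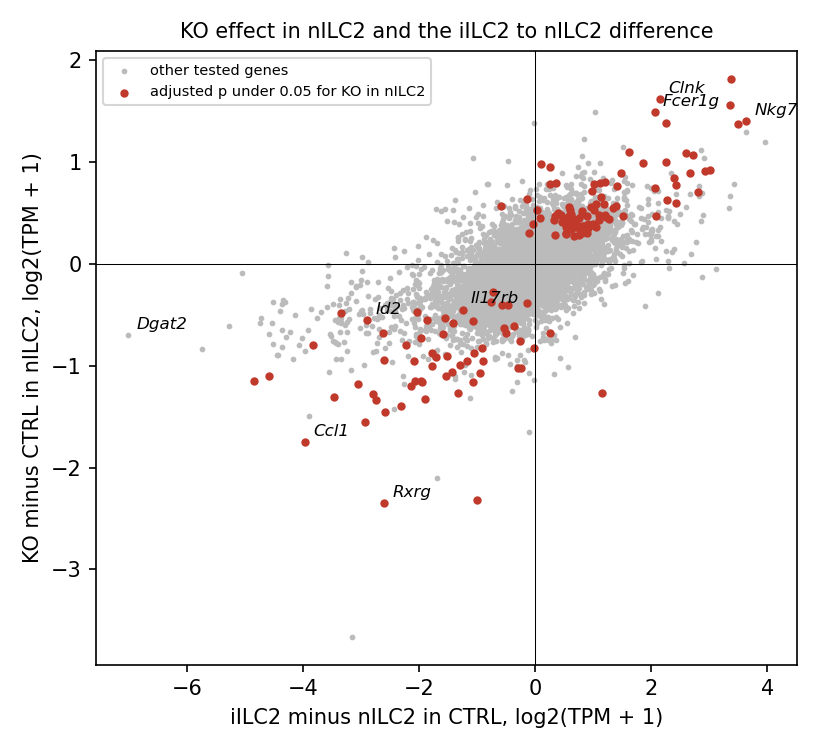
Change by KO in nILC2 against the difference of iILC2 from nILC2 in CTRL, each as log2 fold change per gene. Of the 139 genes called in both, 85 are higher in both and 52 lower in both.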

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

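Chosen only after the results were seen were the tests of a mixture with iILC2 cells, of a single nILC2 KO library, of the spread along the axis from nILC2 to iILC2, of the nILC2 changes in iILC2, of the change over time without IL-25, of splits with equal exchange, of splits that part same-numbered pairs, and of the splits for culture lists in the difference of KO effects.

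The response to IL-25 differed between times for 24 named genes, by the test of the difference itself. From 4 to 48 h the log2 effect moved by -4.54 for Ltb, -3.36 for Gbp2, -2.98 for Tnf, -2.87 for Rora, -2.68 for Relb, -2.51 for Cd83, -1.73 for Dgat2 and -1.52 for Il17rb. It moved by 1.82 for Pparg, 1.37 for Fabp5, 1.32 for Ldha, 1.25 for Tpi1, 1.02 for Pdia6 and 1.02 for Manf. From 48 to 72 h it moved by 3.06 for Tnfrsf9, 2.95 for Gzma, 1.81 for Slc2a3, 1.41 for Prf1, 1.37 for Slc16a3, 1.05 for Scd1, 0.93 for Pgk1, 0.76 for Fdps, -0.84 for Hsp90aa1 and -1.10 for Hspd1.

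The KO nILC2 libraries differed from the CTRL nILC2 libraries in the direction of iILC2. Against iILC2 cells mixed into the KO libraries, genes lower in iILC2 implied a share larger by 0.242 than genes higher in iILC2 did, and against a single library, the difference of the mean scores of KO and CTRL on the axis from nILC2 to iILC2 was 15 and stayed at 11.4 or more without any 1 KO library, with 2 or more of the other KO libraries above every CTRL library. Both gene sets implied a share above 0 in each KO library, with means of 0.108 from the higher and 0.349 from the lower genes. The unequal shares argue against mixture as the sole cause, and a mixture beside another change stays open. Sharing of the nILC2 CTRL libraries and the spread between nILC2 libraries along the axis stay open too. The covariance across genes was 0.140, where simulations with both groups unchanged had a mean of 0.0273, a difference of 0.113, and a highest value of 0.0751. With the CTRL libraries split in 2 sets it was 0.0938 to 0.135, with a mean of 0.115. These values lie above 0.0751, but the simulations with both groups unchanged leave out the iILC2 difference. In 100 simulations with KO unchanged and that difference kept, the highest was 0.139 with separate CTRL libraries. Of these, 4 were at or above 0.0938 and 1 at or above 0.115. With shared CTRL libraries the highest was 0.177 (5 at or above 0.140). On the axis, KO and CTRL differed with an exact permutation p = 0.0571. Whether KO shifts nILC2 toward the iILC2 profile is therefore not settled.

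limma called 155 genes for KO in nILC2, a count for which other splits of the libraries do not exclude chance, and 0 in iILC2, with 328 at an unadjusted p under 0.05, while the difference of the KO effects itself was called for 0 genes, with 1059 at an unadjusted p under 0.05. A larger spread between iILC2 libraries was tested, and their median SD over genes was 0.789 of that between nILC2 libraries (0.194 against 0.246). Their spread was thus not larger. Both KO comparisons used 1 spread per gene, estimated over all 4 groups, so this test cannot decide about the 2 counts. The shared estimate draws on the less variable iILC2 libraries, which may favour calls in nILC2. With the compared groups alone, 5 genes were called in nILC2 and 0 in iILC2. The nILC2 changes were looked for in iILC2 below the threshold, where 154 genes without Rxrg moved in the same direction by a mean of 0.058 (95% interval 0.014 to 0.10), against 0.74 in nILC2. These genes were chosen by their calls in the same nILC2 libraries, which makes 0.74 too high as an estimate of size. The gap between the 2 values is therefore no measure of a difference between the cell types. Deviations shared by same-numbered libraries raise the iILC2 value, and the interval leaves them out, so 0.058 is read only as an upper limit. The test of the difference called 8 genes with the replicate block, 21 with array weights and 5 with the Y-linked term, so whether the effect of KO depends on the cell type stays open. Rxrg was also low in iILC2 before any KO, at 1.62 TPM in CTRL against 2.18 TPM in nILC2 KO. KO minus CTRL was -1.34 TPM in iILC2 and -12.9 TPM in nILC2. The count of 0 in iILC2 thus belongs to a much smaller change of Rxrg.

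NF-kB response genes rose with IL-25 at 4 h, and 13 of 18 lay lower with it at 48 h, where the list did not pass (adjusted p = 0.082) while the change of its effect did. Scaling by a few abundant genes was tested, and the list median at 48 h was -0.38 as deposited, -0.32 after the median of ratios and -0.27 after quantile normalization, with 13 of 18 genes lower each time. A change of the cultures without IL-25 alone was tested as well. From 4 to 48 h the list fell by 2.44 at the median with IL-25 (17 of 18 genes) and by 1.04 without it (16 of 18). The rescaled medians argue against scaling. A rise of the cultures without IL-25 was not seen, as the list fell there. The larger fall with IL-25 restates the change of its effect, so it adds no separate support. A transient NF-kB response to IL-25 may be put forward as a hypothesis found and tested on the same data, which other samples would have to test.

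Single libraries stood apart from the other 3 of their group in 45 of 527 pairs of a gene and a group, judged by the gap to the nearest library divided by the range, and in 0 of 60 pairs of a library statistic and a group. Chance flags about 1 in 20 groups. nILC2 CTRL replicate 2 had 6 such genes and nILC2 KO replicate 1 had 5, more than any other library. For nILC2 CTRL replicate 2 the ratios were 0.983 for Arg1, 0.924 for Fcer1g, 0.906 for Serpina3g, 0.857 for Rom1, 0.852 for Il2ra and 0.843 for Ebp. In nILC2 KO replicate 1 they were 0.925 for Ltb, 0.896 for Serpina3g, 0.885 for Dgat2, 0.849 for Syne4 and 0.84 for Id2. The ratio was 0.866 for Il1rl1 in nILC2 CTRL replicate 1, 0.898 for Tigit in KO replicate 3 and 0.883 for Ifi27l2a in KO replicate 4. In iILC2, it was 0.903 for Dgat2 in CTRL replicate 2 and 0.904 for Lilrb4a in KO replicate 2. iILC2 CTRL replicate 3 had 1 for Lpcat2, 0.949 for Cd83, 0.857 for Nrp1 and 0.841 for Rps27.

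In the 4 h cultures, the ratio was 0.831 for Il17rb in replicate 4 with IL-25. Without IL-25 it was 0.94 for Cpne7, 0.919 for Il5 and 0.847 for Nlrc3 in replicate 3, 0.869 for Klrg1 and 0.836 for Irf4 in replicate 2, and 0.891 for Lrrc52 in replicate 4. At 48 h with IL-25 it was 0.923 for Ctla4 and 0.897 for Fdps in replicate 1, 1 for Cd83 in replicate 2 and 0.832 for Tnfrsf9 in replicate 3. At 48 h without IL-25 it was 1 for Pdzk1ip1, 0.869 for Ube2c and 0.83 for Adora2b in replicate 1, 0.832 for Phgdh in replicate 2, 1 for H2ac19, 0.967 for Cd83 and 0.925 for Sla in replicate 3, and 0.877 for Gbp2 in replicate 4. At 72 h without IL-25 it was 1 for Il10 in replicate 1, 1 for Scd1, 0.854 for Tgtp1, 0.837 for Ltb and 0.8293 for Serpinb1a in replicate 2, and 0.908 for Gzma in replicate 4. A ratio of 1 marks a gene listed at 0 in the other 3 libraries.

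Other splits of the libraries were fitted to ask whether chance can be excluded. For genes called, the real split alone reached its count for IL-25 at 4 h (4250, highest other 69), 48 h (5280 and 98) and 72 h (5113 and 7). The same held for time from 4 to 48 h (6793 and 1269) and 48 to 72 h (40 and 1), and for iILC2 against nILC2 in CTRL (4582 and 0) and KO (3161 and 1). Each is 1 of 35 splits, the smallest share that 35 splits allow. That share is under 0.05, which argues against chance for these counts without excluding it. For time from 48 to 72 h, however, 2 of 35 splits reached the 1226 genes at an unadjusted p under 0.05 (highest other 1572). A fit of the compared groups alone called 3 there, so chance stays open for that comparison. For the change of the IL-25 effect from 4 to 48 h, 3 of 100 drawn splits reached the 2938 genes (highest other 3119). From 48 to 72 h, 6 of 100 reached the 1553 (highest other 4245). The other splits that reached these counts exchange unequal numbers of libraries at the 2 times and so carry the effect of IL-25 itself. The 100 splits therefore cannot decide about chance for either count. Among the 39 and 40 drawn splits with equal exchange, the real one alone reached its count (highest other 0 for both). This argues against chance for both counts, in a test chosen after the results were seen. For KO in nILC2, 2 of 35 splits reached the 155 genes, so chance cannot be excluded. The other, with 746, set CTRL replicate 2 and KO replicates 2, 3 and 4 against CTRL replicates 1, 3 and 4 and KO replicate 1, and points to a structure of the samples beside genotype. The Rxrg level of 17.4 TPM in that CTRL library and 2.58 TPM in that KO library argues against exchanged labels. For KO in iILC2 all 35 splits reached the real count of 0 (highest other 0), and for the difference of KO effects all 100 did (0, highest other 21).

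For gene lists called, the real split alone reached its count for IL-25 at 72 h (1 of 35 splits, 11 lists, highest other 10). It did so too for the change of that effect from 48 to 72 h (1 of 100, 14 and 10) and time from 4 to 48 h (1 of 35, 9 and 7). Of these lists, 4, 4 and 1 were called with an estimated correlation. The shares are under 0.05, but other splits still called up to 10, 10 and 7 lists, so these counts do not exclude chance. For time from 48 to 72 h (1 of 35, 8 and 6) it stays open, as 0 of the 8 were called with an estimated correlation or by fry. It cannot be excluded for IL-25 at 4 h (4 of 35, 9 and 9) and 48 h (6 of 35, 9 and 11), KO in nILC2 (2 of 35, 11 and 11) and in iILC2 (20 of 35, 2 and 8), the difference of KO effects (11 of 100, 9 and 13), and iILC2 against nILC2 in CTRL (6 of 35, 10 and 10) and KO (3 of 35, 12 and 12). For the change of the IL-25 effect from 4 to 48 h (5 of 100, 10 and 10) it stays open, as the others again exchange unequal numbers, and of 39 with equal exchange the real split alone reached 10 (highest other 9). For the 6 culture lists in nILC2 KO, the real split alone reached 6 (1 of 35, highest other 5). That count cannot go higher, and it was 5 with a pseudocount of 0.1 TPM, quantile normalization or the Y-linked term and 0 with an estimated correlation, so chance is not excluded. Nor is it for KO in iILC2 (35 of 35, 0 and 5) or iILC2 against nILC2 in CTRL (7 of 35, 5 and 6) and KO (29 of 35, 4 and 6). For the difference of KO effects the real split alone again reached 6 (1 of 100, highest other 5), the highest count possible, and 0 were called with an estimated correlation or by fry, so chance is not excluded there either. Same-numbered nILC2 KO and iILC2 KO libraries form pairs that deviated together by their correlations. Among the 8 splits that part all 4 of these pairs, too few for a share under 0.05, the real split alone reached its 3161 genes (highest other 0) and 12 lists (10), and 7 reached its 4 culture lists (5).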

How the results depend on the processing

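Only the term for Y-linked expression was chosen after the data were seen. Counts of genes called for IL-25 at 4, 48 and 72 h, for both changes of its effect, for time from 4 to 48 h and for iILC2 against nILC2 in CTRL and KO stayed within 1.5 times the reported counts under every alternative. Without 1 library they were 3799 to 3991, 4841 to 5155, 4569 to 5000, 2695 to 2838, 1313 to 1592, 6365 to 6674, 4135 to 4501 and 2736 to 3206. KO in iILC2 gave 0 genes throughout. For time from 48 to 72 h (40 genes) the count was 26 with a pseudocount of 0.1 TPM, 86 after quantile normalization, 3 in a fit of the compared groups alone, 64 with array weights and 11 to 49 without 1 library. For KO in nILC2 (155) it was 82 with a pseudocount of 0.1 TPM, 272 after the median of ratios, 5 with the compared groups alone, 275 with array weights, 317 with the replicate block, 87 with the term for Y-linked expression and 12 to 1003 without 1 library. For the difference of KO effects (0 by limma, 1059 at an unadjusted p under 0.05) it was 1 after quantile normalization, 21 with array weights, 8 with the replicate block, 5 with the Y-linked term and 0 to 132 without 1 library. A fit of fewer groups has fewer libraries to estimate the spread. For KO in nILC2 it also leaves out the iILC2 libraries, whose median SD over genes was lower (0.194 against 0.246 in nILC2). The count of 5 is therefore not only a matter of fewer libraries, and the share of each was not tested. For the other settings the cause was not tested. The block changed no other count of genes by more than 1.5 times. Of 114 gene list calls, 112 held with it and 1 was gained; those lost were of p53 targets and apoptosis for the change of the IL-25 effect from 48 to 72 h (adjusted p = 0.055) and of the unfolded protein response for KO in nILC2 (adjusted p = 0.051). Same-numbered libraries correlated by over 0.1 in 18 of 24 pairs of the genotype table (-0.04 to 0.25), and 13 of 16 libraries correlated best with their own number. In the culture table these were 3 of 60 pairs (-0.13 to 0.15) and 8 of 24 libraries. A pairing by number is a hint from the data, not the design, also for nILC2 KO and iILC2 KO. Of the 114 list calls, 15 held with an estimated correlation and 84 were among the 140 of fry, and other settings gave 100 to 116. Of 21 calls of culture lists, 5 held with an estimated correlation and 11 were among the 12 of fry; the cause was not tested. The Rxrg difference of KO from CTRL was -12.9 TPM in nILC2 and -1.34 TPM in iILC2, and was -13.9 to -11.8 and -1.46 to -1.25 TPM without 1 library. Across genes, r was 0.07 between the KO effects (0.02 to 0.13 without 1 library) and 0.62 between KO in nILC2 and the iILC2 difference (0.51 to 0.68). The depth of the libraries is unknown, so what depth limits could not be stated.

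Of 251 calls of named genes in a comparison, 213 held in every alternative, 38 were lost in at least 1 and 0 changed direction. Among 27 named results that were not called, 8 passed in some alternative and 10 changed sign, and the cause was not tested. With IL-25 at 4 h, Il1rl1 was -0.023 and Klrg1 -0.12 after quantile normalization, and Gata3 was 0.0097 after the median of ratios. Gata3 passed as lower there after quantile normalization (-0.27, adjusted p = 0.0053), Klrg1 passed as higher after the median of ratios (0.15, adjusted p = 0.026), and at 48 h Il1rl1 passed as higher after the median of ratios (0.26, adjusted p = 0.033). Without 1 library at 4 h, Il1rl1 was -0.016 to 0.11 and Klrg1 -0.030 to 0.018. At 72 h Abcg1 was 0.11 after the median of ratios and 0.10 after quantile normalization. For KO in iILC2, values without 1 library were -0.069 to 0.39 for Il1rl1, -0.016 to 0.083 for Gata3, -0.39 to 0.16 for Il13, -0.25 to 0.17 for Areg, -0.029 to 0.063 for Klrg1 and -0.012 to 0.033 for Cox8a.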

Other observations

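Genes outside the fixed rule, named here, were chosen after their values were seen. The neuropeptide receptor genes Nmur1 and Vipr2 were lower with IL-25 at 4 h and lower in iILC2 than in nILC2. Nmur1, the neuromedin U receptor gene, was 73 ± 18.2 TPM with IL-25 against 178 ± 10.9 without at 4 h (adjusted p = 5.65e-10), 206 ± 13.6 against 377 ± 32.7 at 48 h (adjusted p = 2.39e-07) and 437 ± 23.5 against 463 ± 37.9 at 72 h (adjusted p = 0.57). Vipr2, a receptor gene for vasoactive intestinal peptide, was 11 ± 1.95 against 38.8 ± 4.90 at 4 h (adjusted p = 1.44e-07). In CTRL mice, iILC2 had Nmur1 at 104 ± 10.2 against 352 ± 34.1 TPM in nILC2, and Vipr2 at 5.40 ± 1.25 against 68.8 ± 13.5.

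Markers of other cell types were present at levels that varied with the group. Hba-a1, an alpha globin gene, was 68.9 ± 5.72, 479 ± 21.8 and 622 ± 93.7 TPM at 4, 48 and 72 h without IL-25, while Gata1, a transcription factor gene of red blood cell precursors, was 0.227 ± 0.330, 3.05 ± 0.881 and 2.08 ± 0.830. Cd3g, a T cell receptor subunit gene, was 110 ± 21.3 TPM at 48 h without IL-25, where Cd3e was 2.64 ± 0.472. Cd79b, a B cell receptor subunit gene, was 142 ± 11.4 TPM at 72 h with IL-25 and 256 ± 18.7 in iILC2 of CTRL mice. Epcam, an epithelial gene, was 176 ± 7.06 TPM at 4 h without IL-25 and 92.1 ± 5.62 with it (adjusted p = 1.41e-09). Pecam1, an endothelial and leukocyte adhesion gene, was 152 ± 6.27 TPM at 4 h with IL-25 and 36.1 ± 4.29 without (adjusted p = 8.76e-11). The marker lists of T cells, B and plasma cells, myeloid cells, mast cells and stromal cells had fewer than 3 tested genes each and were not tested, and no mitochondrial gene was listed. The lists of retinoid receptors and of adhesion genes were called in no comparison (adjusted p of 0.094 or more and 0.25 or more).

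In the first principal component of the genotype experiment, nILC2 KO replicate 1 lay at -39.3, within the CTRL range of -47.5 to -35.4, and the other KO libraries lay at -23.0 to -16.3. On the second component, replicate 1 was low in each of the 4 groups, at -10.4, -24.2, -10.7 and -13.5. The libraries with no more than 0.59 TPM over 4 Y-linked genes carried the same replicate numbers in nILC2 and in iILC2, which is a hint from the data, not from the labels, that same-numbered libraries of a genotype shared animals. Between nILC2 KO and iILC2 CTRL, however, r was 0.243, 0.124, 0.126 and -0.0186 for numbers 1 to 4. Shared animals cannot give deviations shared across genotypes, so what same-numbered libraries had in common is not settled. All 24 culture libraries had Y-linked expression, with Eif2s3y at 72.5 to 108 TPM.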
